A study of Caenorhabditis elegans with 8 samples.

How the data were processed

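RNA of whole L4 worms was measured in 16 libraries, 2 replicate libraries in each of 8 groups: wild type and damt-1, each untreated and treated with 1.92 µM antimycin A and labelled P0, F1 or F2. The authors deposited 1 workbook per treated group, with a count sheet and a comparison sheet. The deposited count values are raw counts per RefSeq transcript, read from the values as whole numbers, and each of the 6 count tables holds 2 untreated and 2 treated libraries. Per the submitters' processing notes, Trimmomatic 0.35, HISAT2 2.0.5, SAMtools 1.3.1, HTSeq 0.9.1, R 3.5.0, DESeq2 1.20.0 and the genome build ce10 were used, without a role or order for each. The notes do not say whether duplicate reads were removed. The deposited log2 values are fold changes of treated over untreated, written by DESeq2 per the file headers, and the deposited p-value column is the adjusted p that DESeq2 writes, per the file headers. The deposited wild type comparison tables list only fold changes above 0. The 24 per-sample columns of the comparison tables were not used, since the raw counts were at hand. The authors' deposited tables were used only for their number of calls.

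The count tables list 14396 transcripts in all and 12654 in all 6 tables. Transcripts with a sum of 10 or fewer counts over the 4 libraries of a table are not listed in it, and a transcript missing from a table was left untested there. The untreated counts were the same in all tables of a genotype (0 differences), so each genotype has 1 untreated group. Names came from the reference for 12629 accessions, and 13815 transcripts (96.0%) had a spliced length. The reference was another build than the authors' one, so names and lengths were taken from it and coordinates were not. Library totals ran from 3541390 to 4365451 counts, and the 10 most counted transcripts held between 1.63% and 1.88% of a library.

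Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group with a minimum count of 10 (12592 transcripts kept), TMM factors, robust quasi-likelihood fits with 1 mean per group over all 16 libraries, and Benjamini-Hochberg adjustment within each comparison at 0.05. The common dispersion was 0.00047, a biological coefficient of variation of 2.18%, and the prior degrees of freedom had a median of 14.7. Every adjusted p in the text for a gene is from this edgeR test unless another tool is named. Comparisons were each treated group against its untreated group, damt-1 against wild type in each condition, the genotype by treatment interaction per generation, and F1 and F2 against P0 within genotype. F2 against F1 was added after the data were seen. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with the correlation estimated from the data and with fry. Before the data were examined 38 lists were fixed, and 37 with at least 3 tested members were tested. A list of furrow collagens was added later. Overlaps between genotypes were tested with Fisher's exact test, and overlaps between generations were set beside 50 simulated draws of unchanged groups that share their untreated libraries. Figures were drawn with matplotlib 3.10.9, and log2 CPM for the principal components used the default prior count of edgeR.

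The genes to name were chosen by a rule fixed before the data were examined. It names damt-1, hsp-6, hsp-60, gst-4, sod-3, hsp-16.2, hsp-4, vit-2 and col-19 where tested. In each treated against untreated, untreated genotype and interaction comparison it adds the 6 largest rises and 6 largest falls past the threshold, with a mean of at least 10 CPM in the higher group and both replicates of a group above both of the other (for interactions, at least 10 CPM in some group). Between generations it adds 3 in each direction, and per described list up to 4 members with the smallest adjusted p. For a group with 0 counts, folds are bounds against a floor of 3 counts over its 2 libraries, and for 1 to 3 counts ratios carry an exact 95% counting interval. The fitted log2 of a gene with a group at 0 depends on the prior count and is no bound.

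The pipeline was tested on simulated data built on the wild type P0 comparison. Of 50 changed transcripts per fold, it recovered 15 (30%) at 1.25-fold, 32 (64%) at 1.5-fold, 33 (66%) at 2-fold and 49 (98%) at 4-fold, and it called 8 of 11802 unchanged ones. A raised list was called and 0 of 20 random lists were. Whether replicate numbers pair libraries across groups was checked over 28 pairs of groups: r ran from -0.063 to 0.056, so no block was used. With 2 libraries per group no rule for outlying libraries was applied.

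Alternatives fixed before the data were examined were DESeq2 1.42.0 with its Wald test, RLE factors, library size only, TMM without the sperm, vitellogenin and collagen lists, no count filter, a filter of 10 CPM in 2 libraries, only the groups compared, each library left out in turn, a replicate block, a log2 limit of 1, estimated correlation and fry. Added after the data were seen were an offset for counts per nucleotide, TMM factors from transcripts under 0.2 counts per nucleotide, leaving out the cuticle, moulting and vitellogenin lists, and damt-1 treated against wild type untreated worms. GC content was not checked.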

Results

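Transcript counts were collected by RNA-seq from whole Caenorhabditis elegans of the Bristol background at L4, the last larval stage, grown at 22 °C. The worms were wild type or labelled damt-1, a gene of the methyltransferase-like family linked to adenine methylation of DNA. They were untreated or exposed until L4 to 1.92 µM antimycin A, an inhibitor of complex III of the mitochondrial respiratory chain, and the treated worms were labelled P0, F1 or F2. This gave 8 groups of 2 replicate libraries each, 16 libraries in all. The sources differ on whether exposure began with eggs or with L1 larvae. The labels do not say whether the parents of the F1 and F2 worms were also exposed, so P0, F1 and F2 stand here as labels only. Library totals ran from 3541390 to 4365451 counts, and 12592 transcripts passed the count filter. Each genotype has 1 untreated group, whose 2 libraries serve all 3 of its generations. Levels are library-scaled counts (CPM), given as mean ± SD over the 2 libraries of a group. Log2 differences carry the SE of the fit. Calls are at an edgeR adjusted p under 0.05. Counting intervals and floors cover counting error only. The spread between replicates was small (biological coefficient of variation 2.18%), so the p-values measure only the spread between these libraries, which may have been technical replicates.

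The damt-1 transcript was not lower in the libraries labelled damt-1. It stood at 19.8 ± 0.25 CPM in wild type untreated worms and 19.4 ± 3.4 CPM in damt-1 untreated worms (log2 difference -0.03 ± 0.19, adjusted p = 0.93), and the nature of the mutation is not given. In a principal component analysis of the 16 libraries, the component that held 47.8% of the variance parted the genotypes. The component that held 9.9% set the damt-1 untreated libraries apart, at 39.7 and 41.1. Counts of the densest transcripts stood close to a common ceiling: the 99th percentile was 1.39 counts per nucleotide of transcript, and the highest value 4.1. Of the genes named below, hsp-6 was the densest of the stress markers, at 1.18 counts per nucleotide, and gst-4 stood at 0.74.

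**Figure D1:**
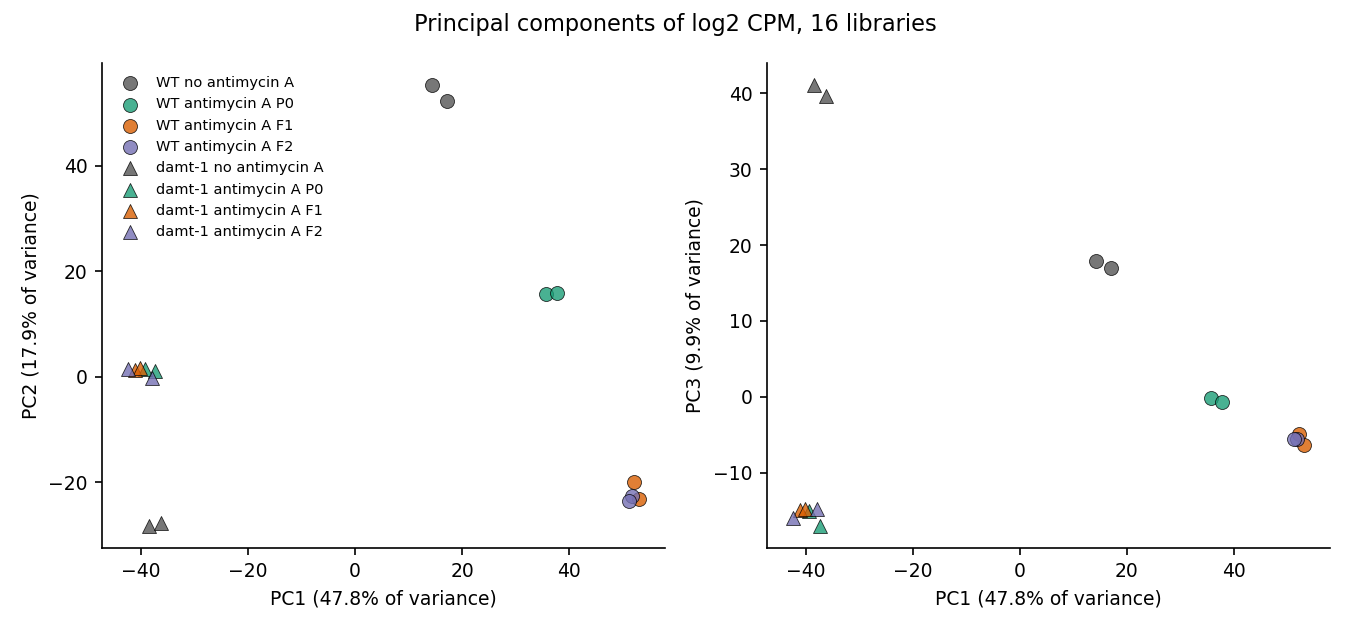
Principal components of log2 CPM, with 1 point per library, circles for wild type, triangles for libraries labelled damt-1, and colours for untreated, P0, F1 and F2. The horizontal axis holds 47.8% of the variance and parts the genotypes, and the vertical axes hold 17.9% (left) and 9.9% (right).

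The comparison of treated P0 with untreated wild type worms asked which transcripts changed with antimycin A. Single genes of several kinds had the largest rises. The cytochrome P450 cyp-14A4 rose 100-fold, from 2.92 ± 1.5 to 302 ± 0.18 CPM (log2 6.65 ± 0.11, adjusted p = 8.3e-23). The acyl-CoA synthetase acs-2, of mitochondrial fatty acid oxidation, rose 40-fold, from 13.4 ± 1.5 to 537 ± 13 CPM (log2 5.32 ± 0.08, adjusted p = 5.1e-23). The C-type lectin clec-17 rose by 6.63 ± 0.17 and gst-14, a glutathione S-transferase, by 6.46 ± 0.28 on the log2 scale. F22B3.7 had 0 counts in the untreated libraries and 118 ± 5.3 CPM after treatment, at least 317-fold higher against a floor of 3 counts over the 2 libraries. The cuticle collagen col-143 had 1 count untreated and 186 treated, a ratio of 186 (95% counting interval 33 to 7400). The mitochondrial superoxide dismutase sod-3, under DAF-16 control, rose 3.68-fold, from 7.62 ± 1.1 to 28.1 ± 2.4 CPM (adjusted p = 2.5e-07).

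Falls in wild type P0 were smaller and included some cuticle genes. Of 135 collagens 22 rose and 39 fell (22 and 45 adjusted over the list alone, camera adjusted p = 0.66), and of 6 adult cuticle genes 2 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.61). The adult cuticle collagen col-19 fell by 0.53 ± 0.05 (241 ± 8.9 to 167 ± 5.8 CPM, adjusted p = 1.9e-08). The 6 largest falls were in try-9, K01A6.7, F47B8.10, T19D12.3, the collagen col-96 and the cuticlin cut-3, from -1.81 ± 0.38 to -1.47 ± 0.46. Among the stress markers, the mitochondrial chaperone hsp-6 rose by 0.18 ± 0.04 (adjusted p = 0.003) and the glutathione S-transferase gst-4 by 0.21 ± 0.06 (adjusted p = 0.0089). The mitochondrial chaperonin hsp-60 differed by 0.19 ± 0.06 (adjusted p = 0.054), hsp-4, the chaperone of the endoplasmic reticulum, by -0.05 ± 0.04 (adjusted p = 0.52), damt-1 by 0.39 ± 0.18 (adjusted p = 0.13) and the yolk protein gene vit-2 by 0.46 ± 0.36 (adjusted p = 0.42), none past the threshold. The heat shock gene hsp-16.2 was not among the transcripts listed.

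By gene list, the smallest camera p in wild type P0 worms was that of cytochromes P450, of which 28 rose and 7 fell of 60 tested (31 and 8 adjusted over the list alone, camera adjusted p = 1.4e-16, adjusted p = 0.00016 with an estimated correlation). Among them, cyp-33C8 rose by 2.8 ± 0.06 and cyp-14A1 by 4.25 ± 0.12. UDP-glucuronosyltransferases, which conjugate foreign compounds, rose in 12 and fell in 7 of 52 (13 and 7 adjusted over the list alone, camera adjusted p = 0.00038, adjusted p = 0.036 with an estimated correlation). Here ugt-61 was at 2.3 ± 0.08 and ugt-19 at 1.95 ± 0.06. Of 16 germ line genes 11 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 3.2e-06, adjusted p = 0.026 with an estimated correlation). They included the P granule helicases glh-4 (0.73 ± 0.07) and glh-1 (0.31 ± 0.04), the translational repressor gld-1 (0.47 ± 0.06) and the Notch receptor glp-1 (0.46 ± 0.08). The 5 tested vitellogenins, yolk proteins made in the intestine, went both ways: vit-5 rose by 1.83 ± 0.05 and vit-1 by 0.6 ± 0.05, while vit-3 fell by 0.25 ± 0.05 (the same 2 and 1 adjusted over the list alone, camera adjusted p = 1.4e-08, adjusted p = 0.028 with an estimated correlation).

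Further lists were called in wild type P0 by camera with its preset correlation and not with an estimated one. The mitochondrial unfolded protein response, chaperones, proteases and import subunits that answer misfolding in mitochondria, rose in 8 and fell in 0 of 15 (12 and 0 adjusted over the list alone, camera adjusted p = 0.00038, adjusted p = 0.16 with an estimated correlation). Its clearest members were the proteases spg-7 (0.36 ± 0.04), lonp-1 (0.28 ± 0.04) and ymel-1 (0.29 ± 0.05) and the import subunit timm-23 (0.34 ± 0.05). Oocyte and eggshell genes rose in 10 and fell in 0 of 17 (11 and 0 adjusted over the list alone, camera adjusted p = 6.7e-05, adjusted p = 0.09 with an estimated correlation), among them the eggshell proteoglycan cpg-2 (0.79 ± 0.07) and the chitin synthase chs-1 (0.91 ± 0.12). Small RNA inheritance genes rose in 8 and fell in 0 of 18 (10 and 0 adjusted over the list alone, camera adjusted p = 8.3e-05, adjusted p = 0.12 with an estimated correlation), including the Argonautes prg-1 (0.58 ± 0.05), wago-1 (0.45 ± 0.04) and hrde-1 (0.5 ± 0.05). Lipid metabolism genes rose in 6 and fell in 2 of 25 (6 and 2 adjusted over the list alone, camera adjusted p = 8.6e-06, adjusted p = 0.12 with an estimated correlation), led by acs-2. Immune effectors rose in 32 and fell in 12 of 154 (32 and 13 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.09 with an estimated correlation). DAF-16 targets of insulin signalling rose in 4 and fell in 1 of 12 (the same adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.16 with an estimated correlation), with the metallothionein mtl-1 at 4.93 ± 0.33. ABC transporters rose in 8 and fell in 2 of 21 (the same adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.47 with an estimated correlation). Here pgp-10 was at 1.96 ± 0.17.

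In all, 1626 transcripts rose and 1017 fell of 12498 tested in wild type P0, 389 and 85 of them by at least 2-fold. Without P0 replicate 2, 1139 rose and 654 fell. DESeq2 called 1489, 1038 risen and 451 fallen, and the authors' deposited table, which lists only positive fold changes for wild type, holds 816 past its adjusted p of 0.05. The split depends on the scaling: with TMM factors taken from transcripts under 0.2 counts per nucleotide, an alternative added after the data were seen, 1293 rose and 1275 fell, with the median of all transcripts moved by -0.051.

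Treated F1 and F2 wild type worms were compared with the same untreated libraries to see which transcripts differed in the later labelled generations. Levels of sod-3 rose further than in P0, to 64.3 ± 0.98 CPM in F1 (log2 3.08 ± 0.18, adjusted p = 1.2e-12) and 66.4 ± 1.6 CPM in F2 (3.13 ± 0.18, adjusted p = 8.7e-13). Levels of cyp-14A4 were 377 ± 8.6 and 379 ± 2.2 CPM, acs-2 at 546 ± 12 and 571 ± 10 CPM. F22B3.7 was at least 467-fold higher in F1 and 503-fold in F2. Other transcripts with 0 untreated counts were C04C3.14 (at least 32.7-fold in F1 and 39.5-fold in F2), ZK177.9 (35.2-fold and 38.2-fold), chil-18, of the chitinase-like family (34.9-fold in F1), and the transthyretin-like ttr-21 (31.2-fold in F2). The transferase gst-14 rose by 6.95 ± 0.26 and 7.04 ± 0.25. The collagen col-19 fell by 1.28 ± 0.06 to 99.5 ± 7.7 CPM in F1 and by 1.38 ± 0.06 to 92.4 ± 7.8 CPM in F2 (adjusted p = 5.4e-15 and 2e-15).

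Among the other largest falls in wild type F1 were B0334.13 (-2.95 ± 0.37), cut-3 (-2.35 ± 0.51), Y47G6A.30 (-2.35 ± 0.43), E03H4.4 (-2.35 ± 0.16), the collagen col-137 (-2.3 ± 0.12) and K01A6.7 (-2.25 ± 0.54). In F2 they were F47B8.10 (-3.36 ± 0.59), B0334.13 (-3.29 ± 0.39), C43F9.11 (-2.44 ± 0.29), ephx-1 (-2.36 ± 0.42), the C-type lectin clec-242 (-2.32 ± 0.2) and the lipase-like lips-6 (-2.31 ± 0.22). The chaperone hsp-6 rose by 0.21 ± 0.04 and 0.24 ± 0.04, hsp-60 by 0.19 ± 0.06 and 0.27 ± 0.06, and gst-4 by 0.31 ± 0.06 and 0.34 ± 0.06 in F1 and F2. In both, hsp-4 fell by 0.19 ± 0.04. The damt-1 transcript rose by 0.67 ± 0.17 in F1 (adjusted p = 0.0024) and 0.61 ± 0.17 in F2 (adjusted p = 0.0057), and vit-2 differed by 0.42 ± 0.36 and 0.4 ± 0.36 (adjusted p = 0.36 and 0.4).

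Cytochromes P450 rose in 39 and fell in 10 of 64 in F1 (40 and 10 adjusted over the list alone, camera adjusted p = 1.7e-09, adjusted p = 0.0032 with an estimated correlation) and in 40 and 9 of 64 in F2 (42 and 13 adjusted over the list alone, camera adjusted p = 4.6e-09, adjusted p = 0.0014 with an estimated correlation). Germ line genes rose in 15 of 16 in each of F1 and F2, with 0 fallen (15 and 0 adjusted over the list alone, camera adjusted p = 3.8e-07 and 1.6e-06, adjusted p = 0.016 and 0.021 with an estimated correlation), and glh-4 went from 106 ± 4.9 CPM untreated to 202 ± 7.8 and 212 ± 13 CPM. Oocyte and eggshell genes rose in 15 and fell in 1 of 17 in both (the same adjusted over the list alone, camera adjusted p = 5.4e-08 and 1.2e-08, adjusted p = 0.03 and 0.023 with an estimated correlation). Here cpg-2 was at 215 ± 2.8 and 223 ± 5.7 CPM against 82.4 ± 3.7 CPM untreated. These 3 lists kept their direction under every scaling tried.

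The cuticle collagens fell in 86 and rose in 24 of 135 in F1 (90 and 24 adjusted over the list alone, camera adjusted p = 0.00022, adjusted p = 0.55 with an estimated correlation) and in 78 and 26 of 136 in F2 (the same adjusted over the list alone, camera adjusted p = 0.001, adjusted p = 0.63 with an estimated correlation). Those that rose included col-176 (2.84 ± 0.06 in F1, 2.88 ± 0.06 in F2) and col-142 (3.05 ± 0.08 and 3.08 ± 0.08). The furrow collagens, made early in each larval cuticle cycle, were a list added after the data were seen. They rose in 5, 6 and 6 of 6 in P0, F1 and F2, with 0 fallen (medians 0.84, 1.51 and 1.54). A difference in stage between treated and untreated wild type worms is thus not excluded. The 6 adult cuticle collagens fell in 5 and rose in 1, bli-1 (0.22 ± 0.04 and 0.25 ± 0.04), in each generation (the same adjusted over the list alone, camera adjusted p = 0.03 and 0.029, adjusted p = 0.18 and 0.2 with an estimated correlation). Small RNA inheritance genes rose in 13 and fell in 1 of 18 in F1 (the same adjusted over the list alone, camera adjusted p = 6.6e-05, adjusted p = 0.18 with an estimated correlation) and in 12 and 1 in F2 (the same adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.2 with an estimated correlation), with hrde-1 going from 188 ± 2.5 CPM to 323 ± 22 CPM in F2 and prg-1 from 218 ± 15 to 415 ± 8 CPM. The mitochondrial unfolded protein response rose in 12 and fell in 0 of 15 in both generations (12 and 13 with 0 fallen, adjusted over the list alone, camera adjusted p = 0.0058 and 7e-04, adjusted p = 0.28 and 0.2 with an estimated correlation). Here spg-7 was at 0.52 ± 0.04 and 0.56 ± 0.04.

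Some cell type markers were called by camera in treated F1 and F2 wild type worms, none of these lists with an estimated correlation. Of 7 neuronal markers 5 fell in F1 and 6 in F2, with 0 risen (the same adjusted over the list alone, camera adjusted p = 0.03 and 0.04, adjusted p = 0.37 and 0.38 with an estimated correlation), among them the dense core vesicle gene ida-1 at -0.55 ± 0.04 in each. Of 9 pharyngeal markers 5 rose and 2 fell in each (the same adjusted over the list alone, camera adjusted p = 0.045 and 0.048, adjusted p = 0.18 and 0.2 with an estimated correlation), with the pharyngeal myosin myo-1 at 1.1 ± 0.07 and 1.09 ± 0.07. DAF-16 targets rose in 7 and fell in 2 of 12 in F1 and in 6 and 2 in F2 (the same adjusted over the list alone, camera adjusted p = 0.03 and 0.029, adjusted p = 0.21 and 0.2 with an estimated correlation). Vitellogenins rose in 2 and fell in 2 of 5 in each (the same adjusted over the list alone, camera adjusted p = 0.011 and 0.012, adjusted p = 0.21 and 0.22 with an estimated correlation). Here vit-5 was at 2.12 ± 0.05 and 2.14 ± 0.05. UDP-glucuronosyltransferases rose in 20 and fell in 15 of 54 in F1 and in 18 and 16 in F2 (22 and 15, then 19 and 16, adjusted over the list alone, camera adjusted p = 0.027 and 0.034, adjusted p = 0.18 and 0.2 with an estimated correlation), and their median of 0.11 and 0.08 turned to -0.03 and -0.05 with the low-density TMM factors, as the values of all transcripts moved. Lipid metabolism genes rose in 9 and fell in 6 of 25 in F2 (10 and 6 adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.38 with an estimated correlation), with a median of 0.08 that turned to -0.05 with the same factors for the same reason.

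In wild type F1, 3290 transcripts rose and 2600 fell of 12559 tested, and in F2 3246 rose and 2635 fell of 12548, 1085 and 478 and then 1074 and 562 of them by at least 2-fold. The authors' deposited tables hold 2158 and 2186 rises past their adjusted p of 0.05. With the low-density TMM factors 2367 rose and 4048 fell in F1 and 2455 rose and 3694 fell in F2, with the median of all transcripts moved by -0.149 and -0.128, so changes of that size are relative to the scaling.

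**Figure D2:**
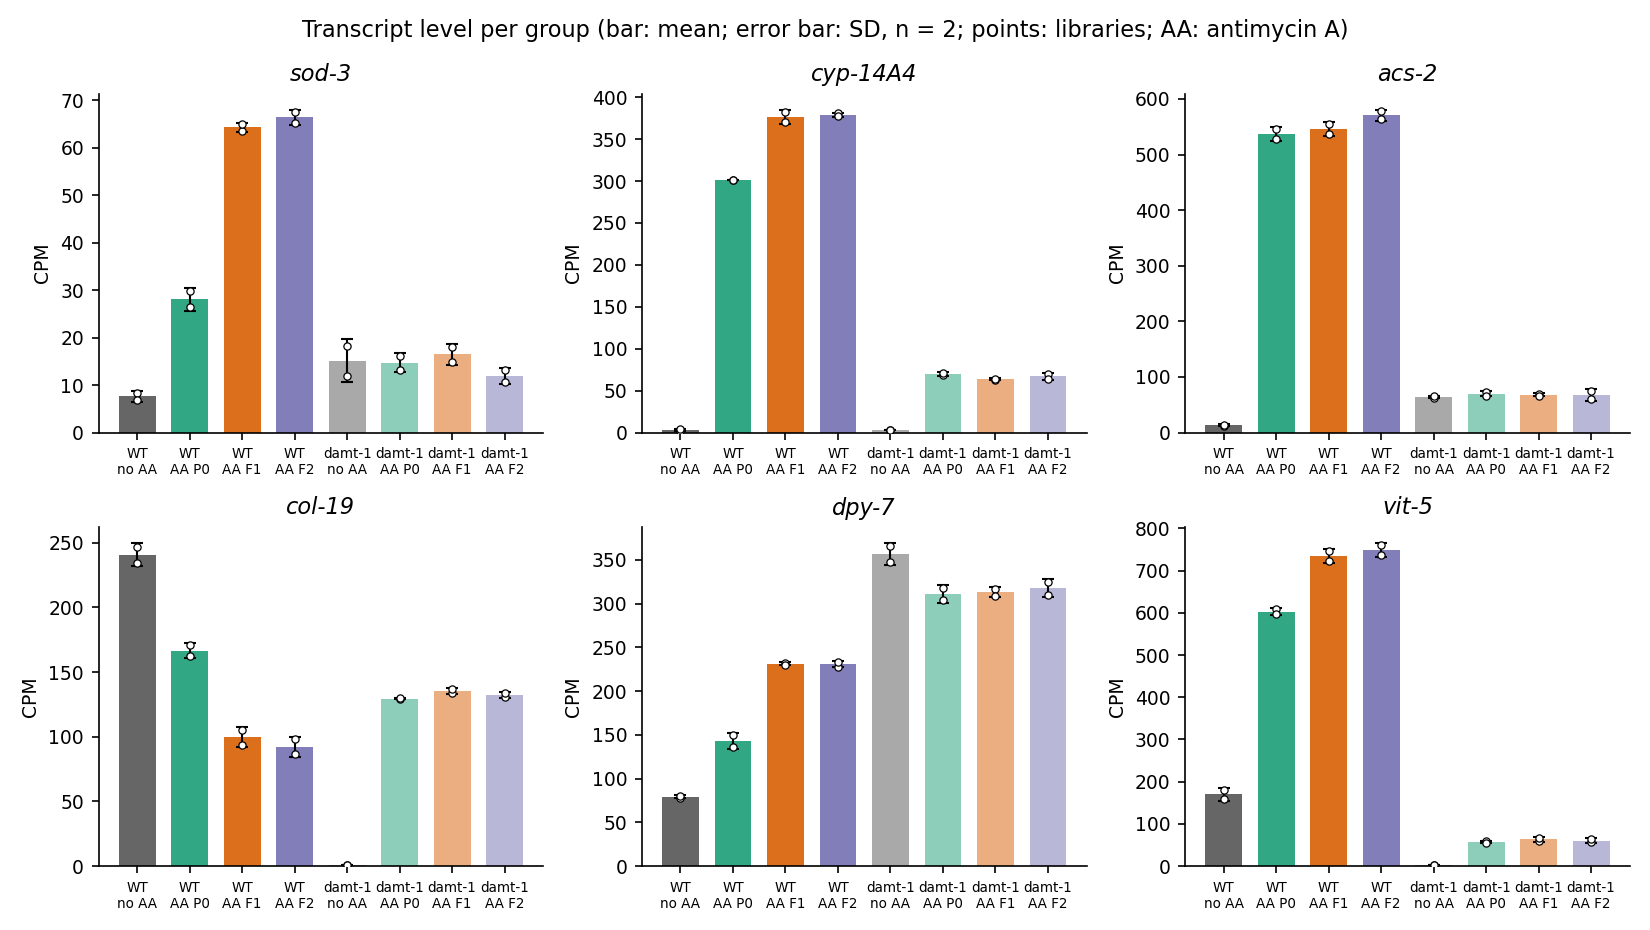
Level in CPM of 6 transcripts in each of the 8 groups (bar: mean, error bar: SD, n = 2, points: libraries). Levels of sod-3 reached 66.4 CPM in wild type F2 and 11.9 CPM in damt-1 F2, while col-19 stood at 241 CPM in wild type untreated and 0.523 CPM in damt-1 untreated worms.

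The treated wild type generations were also compared with each other. F1 differed from P0 in 2798 transcripts, 1525 higher and 1273 lower of those tested, and F2 from P0 in 2809, 1516 higher and 1293 lower. With the low-density TMM factors 2090 of 3025 calls were lower in F1 and 1778 of 2777 in F2, with the median of all transcripts moved by -0.098 and -0.077, so which direction held more calls depended on the scaling. It also depended on a library: without replicate 2 of F1, 794 were higher and 839 lower in F1. The dismutase sod-3 was higher in F1 and F2 than in P0 by 1.2 ± 0.14 and 1.24 ± 0.14 (adjusted p = 9.1e-07 and 4.8e-07), and col-19 was lower by -0.75 ± 0.06 and -0.85 ± 0.06. The largest differences upward were F08D12.3 (3.57 ± 0.27 and 3.41 ± 0.28), M163.8 (3.49 ± 0.5 and 3.46 ± 0.5) and W01C9.2 (3.41 ± 0.53 and 3.45 ± 0.53). Downward in F1 they were C15C8.5 (-1.91 ± 0.3), dct-5 (-1.7 ± 0.29) and the neuropeptide-like nlp-25 (-1.61 ± 0.32), and in F2 F31B12.3 (-1.55 ± 0.36), C01G12.7 (-1.55 ± 0.33) and F09E5.12 (-1.51 ± 0.28). The chaperone hsp-4 was lower by -0.14 ± 0.04 and -0.15 ± 0.05. Adjusted p for hsp-6, hsp-60, gst-4, damt-1 and vit-2 lay between 0.11 and 0.99.

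Many transcripts moved further in the same direction between the labelled generations. Of the 1626 that rose in P0, 754 (46.4%) were higher again in F1 than in P0 and 41 (2.5%) were lower. Of the 1017 that fell, 525 (51.6%) were lower again and 19 higher. Between P0 and F1, 1546 transcripts rose in both and 937 fell in both, where independent lists of the same sizes would share 422.4 and 211.6, and the log2 changes correlated across genes at r = 0.83. F1 and F2 shared 2892 rises and 2254 falls, at r = 0.94. P0 and F2 shared 1538 rises and 943 falls, at r = 0.83. Genes are not independent replicates, and both sides share their untreated libraries. Sharing alone fixes an r near 0.51 in simulated unchanged groups, so that r does not size the shared part. For P0 and F1 the covariance was 0.461, against a mean of 0.033 in those groups. The simulated groups hold only the spread between replicate libraries. A deviation of the untreated worms as a group would add to the covariance too, so it does not size a shared response.

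Between F2 and F1 of the wild type, edgeR and DESeq2 called 0 transcripts, with 452 and 120 at an unadjusted p under 0.05. Here sod-3 differed by 0.05 ± 0.12 and col-19 by -0.1 ± 0.07. DESeq2 called 1361 between F1 and P0 and 1432 between F2 and P0. Without replicate 2 of wild type F1, edgeR called 1633 between F1 and P0, and without replicate 2 of F2 it called 1801 between F2 and P0, 908 of them higher. Without replicate 1 of P0, 935 were higher and 836 lower in F1 and 973 higher in F2, and without replicate 1 of F2, 857 were lower in F2.

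In worms labelled damt-1, treated groups were compared with damt-1 untreated worms to see which transcripts changed with antimycin A in this genotype. The largest rises were in cuticle and secreted genes that were close to absent in the untreated damt-1 libraries. The adult collagen col-19 went from 0.523 ± 0.023 CPM to 130 ± 0.63, 135 ± 2.4 and 132 ± 2.3 CPM in P0, F1 and F2 (log2 7.87 ± 0.2, 7.93 ± 0.2 and 7.9 ± 0.2, adjusted p from 2.5e-19 to 3.3e-19). Transcripts with 0 untreated counts were col-137 (at least 146-fold, 151-fold and 148-fold higher in P0, F1 and F2), col-62 (69.9-fold, 46.4-fold and 47-fold), abu-1 (83.4-fold, 69.3-fold and 82.7-fold), abu-7 (68.6-fold, 77.5-fold and 60.1-fold), abu-15 (78.1-fold, 80.2-fold and 73.8-fold) and idpc-2 (38.7-fold, 39.9-fold and 41.2-fold), all against the floor of 3 counts. The abu genes encode secreted proteins of a family first described under stress of the endoplasmic reticulum. These folds all rest on the same 2 untreated libraries.

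The largest falls in damt-1 P0 were F31B9.2 (-1.89 ± 0.31), the cuticle collagen dpy-17 (-1.57 ± 0.26), the cytochrome P450 cyp-35A5 (-1.53 ± 0.25), the glypican gpn-1 (-1.49 ± 0.3), dot-1.3 (-1.44 ± 0.32) and Y54G2A.12 (-1.44 ± 0.3). In F1 they were dot-1.3 (-2.11 ± 0.35), ZC84.6 (-1.79 ± 0.27), fbxa-202 (-1.72 ± 0.29), gpn-1 (-1.59 ± 0.31), F28E10.4 (-1.58 ± 0.38) and ZK686.5 (-1.5 ± 0.33), and in F2 oac-23 (-2.21 ± 0.4), gpn-1 (-1.74 ± 0.31), Y54G2A.12 (-1.74 ± 0.32), fbxa-202 (-1.61 ± 0.28), ZC84.6 (-1.55 ± 0.26) and F56D2.3 (-1.5 ± 0.36). The chaperone hsp-4 rose by 0.2 ± 0.05, 0.23 ± 0.05 and 0.24 ± 0.05 in P0, F1 and F2. The transferase gst-4 fell by 0.24 ± 0.06 in P0 (adjusted p = 0.013) and differed by -0.18 ± 0.06 and -0.17 ± 0.06 in F1 and F2 (adjusted p = 0.068 and 0.081). The dismutase sod-3 stood at 15.1 ± 4.5 CPM untreated and 14.8 ± 2.1 and 11.9 ± 1.7 CPM in P0 and F2. Its log2 difference was 0.13 ± 0.2 in F1, and the adjusted p lay between 0.4 and 0.97 over the 3 generations. The chaperone hsp-6 stood at 711 ± 14 CPM untreated and 733 ± 14, 739 ± 17 and 756 ± 49 CPM treated (adjusted p from 0.23 to 0.62). For hsp-60, damt-1 and vit-2 the adjusted p lay between 0.14 and 0.99.

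Detoxification lists rose in damt-1 worms as well. Cytochromes P450 rose in 21 and fell in 7 of 60 in P0, 23 and 6 in F1, and 22 and 7 in F2 (21 and 8, 25 and 10, and 24 and 7 adjusted over the list alone, camera adjusted p = 3.8e-13, 1.9e-12 and 1.3e-11, adjusted p = 0.0012, 0.0011 and 0.0016 with an estimated correlation). The P450 gene cyp-14A4 reached 69.9 ± 2.4 CPM in P0 from 3.13 ± 0.23 CPM, and cyp-33C5 rose by 4.34 ± 0.17. UDP-glucuronosyltransferases rose in 15 and fell in 6 of 53 in P0, 17 and 3 of 52 in F1, and 16 and 5 of 53 in F2 (18 and 7, 18 and 3, and 20 and 5 adjusted over the list alone, camera adjusted p = 4.3e-13, 3.5e-14 and 1.1e-13, adjusted p = 0.0012, 0.0011 and 0.0016 with an estimated correlation), with ugt-1 going from 44.3 ± 5.8 CPM to 518 ± 13 CPM in P0. ABC transporters rose in 7, 5 and 6 and fell in 3 of 21 in each generation (11 and 4, 6 and 3, and 8 and 3 adjusted over the list alone, camera adjusted p = 2.3e-06, 7.7e-05 and 8.4e-06, adjusted p = 0.14, 0.16 and 0.15 with an estimated correlation). Here pgp-9 was at 1.85 ± 0.05 in P0. Glutathione S-transferases rose in 7 and fell in 0 of 42 in F1 (the same adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.11 with an estimated correlation). Here gst-33 was at 2.59 ± 0.13.

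Collagens rose in 69, 70 and 70 and fell in 10, 8 and 8 of 129, 130 and 129 tested in damt-1 P0, F1 and F2 (71 and 11, 76 and 10, and 78 and 9 adjusted over the list alone, camera adjusted p = 8.4e-67, 3e-76 and 1e-77, adjusted p = 0.014, 0.011 and 0.0082 with an estimated correlation). Here col-139 was at 5.72 ± 0.11 and col-81 at 5.5 ± 0.12 in P0. The adult cuticle list of 6 rose in 3 in each, col-19, col-62 and col-7, and fell in 1, bli-1, in P0 and F1 (3 and 1 adjusted over the list alone in all 3, camera adjusted p = 6.7e-08, 1.9e-08 and 1.1e-08, adjusted p = 0.0043, 0.0035 and 0.0031 with an estimated correlation). Its median was 3.38, 3.23 and 3.33, or 3.03, 2.77 and 2.77 with members at 0 set to their bound. Germ line genes fell in 8, 9 and 9 of 16 and rose in 0 (12, 9 and 12 adjusted over the list alone, camera adjusted p = 1.1e-05, 0.00011 and 8.3e-06, adjusted p = 0.014, 0.025 and 0.0082 with an estimated correlation), with glh-4 going from 105 ± 1.1 CPM untreated to 67.9 ± 0.37 CPM in P0. Small RNA inheritance genes fell in 5 and rose in 0 of 18 in F1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.38 with an estimated correlation). Here hrde-1 was at -0.5 ± 0.06 and wago-1 at -0.53 ± 0.05.

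Some yolk and eggshell genes rose in damt-1 worms, in lists called by camera alone. Vitellogenins rose in 3 and fell in 1 of 5 in each generation (3 and 1, 4 and 1, and 3 and 1 adjusted over the list alone, camera adjusted p = 0.0035, 0.0014 and 0.003, adjusted p = 0.17, 0.15 and 0.17 with an estimated correlation): vit-5 went from 1.7 ± 0.26 to 56.5 ± 3 CPM in P0, and vit-1 fell by 0.83 ± 0.05. Oocyte and eggshell genes rose in 7 and fell in 0 of 17 in each (8 and 0 adjusted over the list alone, camera adjusted p = 0.013, 0.026 and 0.036, adjusted p = 0.29, 0.34 and 0.43 with an estimated correlation), led by perm-4 (1.87 ± 0.18 in P0), a protein of the eggshell's permeability barrier. Moulting genes went both ways, 9 up and 7, 6 and 4 down of 40 (9 and 8, 10 and 7, and 10 and 6 adjusted over the list alone), with medians of 0.01, -0.04 and 0 against means of 0.33, 0.31 and 0.34 (camera adjusted p = 0.036, 0.021 and 0.0082, adjusted p = 0.17, 0.15 and 0.12 with an estimated correlation), and the P0 median turned to -0.02 when scaled by library size only. Their 2 strongest members were the hedgehog-related genes grd-6 (2.99 ± 0.09 in P0) and wrt-8 (2.88 ± 0.11). The mitochondrial unfolded protein response had 0, 1 and 1 member called of 15, ymel-1 at 0.15 ± 0.05 in F1 and F2, and its camera test passed in none of the 3.

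In total, 1048 transcripts rose and 708 fell of 12460 in damt-1 P0, 956 and 687 of 12432 in F1, and 982 and 726 of 12435 in F2, with 411 and 90, 381 and 87, and 395 and 99 by at least 2-fold. The falls were fewer with a library left out, and fewer still with DESeq2. They became 467, 458 and 458 in P0 without untreated replicate 1, untreated replicate 2 and P0 replicate 1. In F1 they became 425 and 435 without untreated replicate 2 and F1 replicate 1, and in F2 435 and 437 without untreated replicate 2 and F2 replicate 2. Scaled by library size only, 867 rose and 915 fell in F2. DESeq2 called 1034, 1043 and 1020, of them 368, 410 and 380 fallen, and the authors' deposited tables hold 554 rises and 252 falls, 533 and 244, and 443 and 158 past their adjusted p of 0.05. Against wild type untreated worms, an alternative added after the data were seen, the same treated libraries differed in 4504, 4631 and 4646 transcripts. Of the calls against damt-1 untreated worms, 546, 533 and 583 were called the same way there and 711, 682 and 675 the opposite way. This change of control adds the genotype difference by construction, so these counts do not test the damt-1 response.

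The treated damt-1 generations did not part from each other in any call. The mean chi-square per degree of freedom of library pairs across them was 1.28, 1.31 and 1.27, against 1.18 to 1.33 within groups, so libraries from 1 pool of worms or RNA are not excluded. edgeR called 0 transcripts between F1 and P0, F2 and P0, and F2 and F1, with 555, 573 and 519 at an unadjusted p under 0.05, and DESeq2 called 0 with 177, 219 and 176 at an unadjusted p under 0.05. The collagen col-19 differed by 0.06 ± 0.06, 0.03 ± 0.06 and -0.04 ± 0.06, sod-3 by 0.15 ± 0.2, -0.3 ± 0.22 and -0.46 ± 0.22, and hsp-6 by 0.01 ± 0.04, 0.04 ± 0.04 and 0.03 ± 0.04 in these comparisons. P0 and F1 shared 816 rises and 492 falls, P0 and F2 818 and 500, and F1 and F2 806 and 480, at r = 0.89, 0.89 and 0.88 across genes. Independent lists of these sizes would share 79.9 and 39.2, 82.2 and 41.4, and 75.1 and 40.3. The shared untreated libraries alone fix a mean r of 0.5 in simulated unchanged groups. Covariances were 0.45, 0.449 and 0.441, against a mean of 0.033 in those groups. The simulated groups hold only the spread between replicate libraries. A deviation of the damt-1 untreated worms as a group would add to these covariances too, so they do not size a shared response.

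Untreated damt-1 worms were compared with untreated wild type worms to see what the genotype changed before treatment. Some adult cuticle and yolk transcripts were far lower in damt-1, although of 6 adult cuticle genes 2 were higher and 3 lower (the same adjusted over the list alone, camera adjusted p = 0.15). The collagen col-19 fell by 8.76 ± 0.17 (adjusted p = 3.6e-22). The transcript of col-137 was at least 211-fold lower, idpc-2 79.2-fold, F54F7.3 64.9-fold and abu-1 52.3-fold against the floor of 3 counts. In damt-1, col-119 had 1 count against 684 (ratio 650, 95% counting interval 116 to 25700). The yolk gene vit-5 stood at 1.7 ± 0.26 CPM against 170 ± 15 CPM, and vit-2 fell by 1.79 ± 0.48 (adjusted p = 0.0042). The C-type lectin clec-47 was higher by 5 ± 0.13 (136 ± 8.4 against 4.25 ± 0.67 CPM), the lipid-binding lbp-8 by 4.84 ± 0.33 and the collagen dpy-17 by 4.58 ± 0.38. Counts in wild type were 1, 2 and 3 for srlf-35 (ratio 87.3, interval 15.2 to 3490), hsd-3 (48.4, 13 to 406) and the transcript NR_101989 (36.1, 12 to 178). The dismutase sod-3 was higher by 0.99 ± 0.24 (adjusted p = 0.0017) and hsp-60 by 0.27 ± 0.06, and hsp-4 was lower by -0.18 ± 0.05. The chaperone hsp-6 differed by 0.11 ± 0.04 (adjusted p = 0.05) and gst-4 by -0.04 ± 0.06 (adjusted p = 0.65).

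Collagens fell in 74 and rose in 25 of 130 (the same adjusted over the list alone, camera adjusted p = 4.7e-21, adjusted p = 0.32 with an estimated correlation). Vitellogenins fell in 4 and rose in 1 of 5, vit-1 at 0.61 ± 0.05 (the same adjusted over the list alone, camera adjusted p = 2.7e-18, adjusted p = 0.0047 with an estimated correlation), with a median of -4.11. Of 60 sperm genes 44 fell and 0 rose (48 and 0 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.08 with an estimated correlation), including the sperm genes sss-1 (-0.89 ± 0.09) and spe-11 (-1.13 ± 0.15). Oocyte and eggshell genes fell in 13 and rose in 0 of 17 (the same adjusted over the list alone, camera adjusted p = 1e-04, adjusted p = 0.26 with an estimated correlation). Here perm-4 was at -3.1 ± 0.15 and cbd-1 at -1.2 ± 0.1. Lipid metabolism genes rose in 14 and fell in 6 of 25 (14 and 7 adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.45 with an estimated correlation), among them the fatty acid synthase fasn-1 (0.94 ± 0.03) and acs-2 (2.25 ± 0.14).

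Untreated, 2233 transcripts were higher and 2536 lower in damt-1 of 12474 tested, 648 and 1035 by at least 2-fold. With the low-density TMM factors 3079 were higher and 2107 lower, with the median of all transcripts moved by 0.088. The genotypes came in separate tables, so any batch that followed genotype cannot be parted from it. A difference in stage is not excluded either, since 6 of 6 furrow collagens were higher in damt-1 (median 2.18).

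Treated worms of the genotypes were compared within each labelled generation. The yolk gene vit-5 stayed lower in damt-1 by -3.41, -3.54 and -3.63 in P0, F1 and F2, vit-4 by -2.89, -2.49 and -2.58, and the carnitine palmitoyltransferase gene cpt-3 by -4.51, -3.99 and -4.33. The nuclear receptor gene nhr-235 stayed higher by 3.61, 4.14 and 3.75 and the acyl-CoA dehydrogenase gene acdh-2 by 3.83, 4.23 and 3. These 5 genes were chosen after their values were seen, from the 82 transcripts at least 2-fold higher and the 288 at least 2-fold lower in damt-1 under all 4 conditions. List tests of these comparisons, added after the data were seen, had the same 4 lists with the smallest camera p in each generation. Lower members, with 0 higher, were 5 of 5 vitellogenins, 16 of 16 germ line genes and 17 of 17 oocyte and eggshell genes in each (the same adjusted over the list alone), and 44, 55 and 52 of 60 sperm genes (48, 56 and 55 adjusted over the list alone). Camera adjusted p over these lists and generations was at most 2.6e-06, and at most 0.012 with an estimated correlation. Other lists passed both tests. Moulting genes were higher in 16, 19 and 19 and lower in 9, 3 and 4 of 40 (19 and 10, 19 and 3, and 19 and 4 adjusted over the list alone, adjusted p = 0.045, 0.021 and 0.013 with an estimated correlation), and cytochromes P450 lower in 25, 33 and 33 and higher in 15, 15 and 14 of 57, 59 and 59 (28 and 15, 33 and 15, and 35 and 14 adjusted over the list alone, adjusted p = 0.045, 0.015 and 0.0092). In F1 and F2, histones were higher in 21 and 19 and lower in 1 of 30 (the same adjusted over the list alone, adjusted p = 0.031 and 0.027), adult cuticle genes higher in 6 of 6 (the same adjusted over the list alone, adjusted p = 0.028 and 0.021), pharyngeal markers lower in 8 and 7 of 9 with 0 higher (the same adjusted over the list alone, adjusted p = 0.031 and 0.027), and small RNA inheritance genes lower in 12 and 10 and higher in 1 of 18 (13 and 11 lower and 1 higher adjusted over the list alone, adjusted p = 0.029 and 0.027). In P0 these lists did not pass with an estimated correlation but leaned the same way. Histones were higher in 14 and lower in 1, and adult cuticle genes in 4 and 1. Pharyngeal markers were higher in 0 and lower in 5, and small RNA inheritance genes in 1 and 9. The difference between generations was not tested. Lists of other cells and stages thus differed between the genotypes beside the germ line lists, some of them lower and some higher in damt-1. In P0, 1924 transcripts were higher and 2506 lower, in F1 3045 and 3331, and in F2 2883 and 3221. With the low-density TMM factors these became 3546 and 1989, 5325 and 2305, and 5255 and 2302, with the median of all transcripts moved by 0.123, 0.242 and 0.225. Without replicate 2 of wild type F1, 2614 were higher and 2595 lower in F1, and without replicate 2 of wild type F2, 2655 and 2647 in F2. Across genes, the genotype difference in untreated worms correlated with that in P0 at r = 0.43, in F1 at 0.2 and in F2 at 0.18. Furrow collagens were higher in damt-1 in 6 of 6 in treated P0, F1 and F2 (medians 1.23, 0.52 and 0.47). A difference in stage between treated worms of the genotypes is thus not excluded. Any batch that followed genotype cannot be parted from it here either.

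Whether the response to antimycin A differed between genotypes was tested by the interaction. It rests on the untreated group of each genotype, and a difference in stage between these groups is not excluded. The adult collagen col-19 rose with treatment in damt-1 and fell in wild type. Its interaction was 8.4 ± 0.21, 9.21 ± 0.2 and 9.28 ± 0.2 in P0, F1 and F2 (adjusted p from 1.9e-20 to 6.1e-19). The fatty acid oxidation gene acs-2 rose in wild type, while in damt-1 it stood at 64 ± 2.4 CPM untreated and 70 ± 4.8, 68 ± 2.5 and 67.8 ± 11 CPM treated. The acs-2 interactions were -5.19 ± 0.15, -5.26 ± 0.15 and -5.31 ± 0.15. The dismutase sod-3 had interactions of -1.91 ± 0.3, -2.95 ± 0.28 and -3.46 ± 0.29 (adjusted p = 3e-05, 9.8e-09 and 1e-09), gst-4 of -0.45 ± 0.09, -0.49 ± 0.09 and -0.51 ± 0.09, and hsp-4 of 0.24 ± 0.06, 0.42 ± 0.06 and 0.43 ± 0.06. For hsp-6 they were -0.14 ± 0.06, -0.15 ± 0.06 and -0.15 ± 0.06 (adjusted p = 0.11, 0.05 and 0.055). The metallothionein mtl-1 rose to 38.7 ± 5.9 CPM in wild type P0 and stood at 1.43 ± 0.61 CPM in damt-1 P0. The heme-responsive gene hrg-2 reached 58.4 ± 1 CPM in wild type F1 and 2.93 ± 1 CPM in damt-1 F1.

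Germ line genes rose in wild type and fell in damt-1. The interaction was lower in 13, 14 and 16 of 16 and higher in 0 in P0, F1 and F2 (14, 15 and 16 adjusted over the list alone, camera adjusted p = 2.9e-09, 5.3e-08 and 2.2e-08, adjusted p = 0.013, 0.018 and 0.0084 with an estimated correlation). Here glh-4 was at -1.36 ± 0.11, -1.52 ± 0.1 and -1.62 ± 0.11. Small RNA inheritance genes were lower in 8, 11 and 12 and higher in 0, 1 and 1 of 18 (10, 12 and 12 lower and 1 higher in each adjusted over the list alone, camera adjusted p = 0.00014, 4.7e-05 and 0.00023, adjusted p = 0.24, 0.23 and 0.3 with an estimated correlation). Here hrde-1 was at -0.98 ± 0.08, -1.27 ± 0.07 and -1.11 ± 0.07. Collagens were higher in 65, 86 and 81 and lower in 18, 20 and 20 of 128, 129 and 129 (69, 90 and 83 higher and 19, 20 and 20 lower adjusted over the list alone, camera adjusted p = 6.5e-39, 3.6e-33 and 1.6e-31, adjusted p = 0.11, 0.15 and 0.15 with an estimated correlation). Adult cuticle genes were higher in 3, 4 and 4 and lower in 1 of 6 (the same adjusted over the list alone, camera adjusted p = 1.2e-05, 1.7e-05 and 1.4e-05, adjusted p = 0.019, 0.024 and 0.02 with an estimated correlation). Lipid metabolism genes were lower in 6 and higher in 2 of 25 in P0 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0037, adjusted p = 0.42 with an estimated correlation).

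The interaction was called in 2720 transcripts in P0 (1297 higher, 1423 lower), 5005 in F1 (2309 and 2696) and 4968 in F2 (2304 and 2664). DESeq2 called 1737 in P0. With the low-density TMM factors the P0 split became 1365 higher and 1218 lower, the F1 split 3287 higher and 2009 lower and the F2 split 3070 and 2000, with the median of all transcripts moved by 0.035, 0.154 and 0.137.

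Few responses were common to both genotypes. In P0, F1 and F2 they shared 200, 202 and 202 rises, where independent lists would share 134, 246.1 and 250.4 (Fisher's exact test, p = 1.6e-09, 0.00059 and 0.00018), and 34, 52 and 66 falls against 57.9, 143.4 and 153.5 (p = 4e-04, 1.8e-22 and 5.2e-19). Only the P0 rises were thus in excess. Of 12298 transcripts tested in all 6 treated against untreated comparisons, 129 rose in all 6 and 24 fell in all 6. The sets called in all 3 generations of each genotype, taken as independent between genotypes only, would share 88.9 and 31.5. Those that rose took in 10 of 56 cytochromes P450 (Fisher's exact test, adjusted p = 9.9e-09), 8 of 51 UDP-glucuronosyltransferases (adjusted p = 9.5e-07), 5 of 17 oocyte and eggshell genes (adjusted p = 8.1e-06), 7 of 152 immune effectors (adjusted p = 0.01) and 2 of 9 pharyngeal markers (adjusted p = 0.028), and those that fell 2 of 9 hypoxia and sulfide genes (adjusted p = 0.0048) and 2 of 21 ABC transporters (adjusted p = 0.014). The oocyte and eggshell interaction was higher in 3, 2 and 2 and lower in 3, 11 and 10 of 17 in P0, F1 and F2 (3 and 3, 2 and 11, and 2 and 12 adjusted over the list alone, camera adjusted p = 1, 0.25 and 0.22). The 129 transcripts that rose in all 6 included cyp-14A4, gst-14, cyp-13A6, vit-5 and ugt-61. The last was at 2.3, 2.83 and 2.84 in wild type and 2.69, 2.73 and 2.75 in damt-1. Opposite responses were more frequent than sets independent between the genotypes would give: 248 transcripts rose in all 3 wild type and fell in all 3 damt-1 comparisons (51.2 by such sets), among them 8 of 16 germ line genes (adjusted p = 1e-08) and 4 of 18 small RNA inheritance genes (adjusted p = 0.0073), and 272 went the other way (54.7), among them 33 of 127 collagens (adjusted p = 6.4e-25) and 7 of 40 moulting genes (adjusted p = 0.00044). The laminin subunit lam-3 rose by 1.36, 3.59 and 3.51 in wild type and fell by 1.04, 0.92 and 1.24 in damt-1. Across genes the responses of the genotypes correlated at r = -0.06 in P0, -0.19 in F1 and -0.17 in F2. The 3 comparisons of a genotype share 1 untreated group. Fisher's exact test takes transcripts as independent, which they are not, so its p-values here can overstate the evidence. With an estimated correlation, the interaction of germ line genes passed camera, and those of collagens and small RNA inheritance genes did not. Furrow collagens were higher in damt-1 than in wild type untreated worms (median 2.18). A difference in stage between the untreated groups is thus not excluded as a source of opposite responses. The genes cyp-13A6, ugt-61 and lam-3 were chosen after their values were seen.

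**Figure D3:**
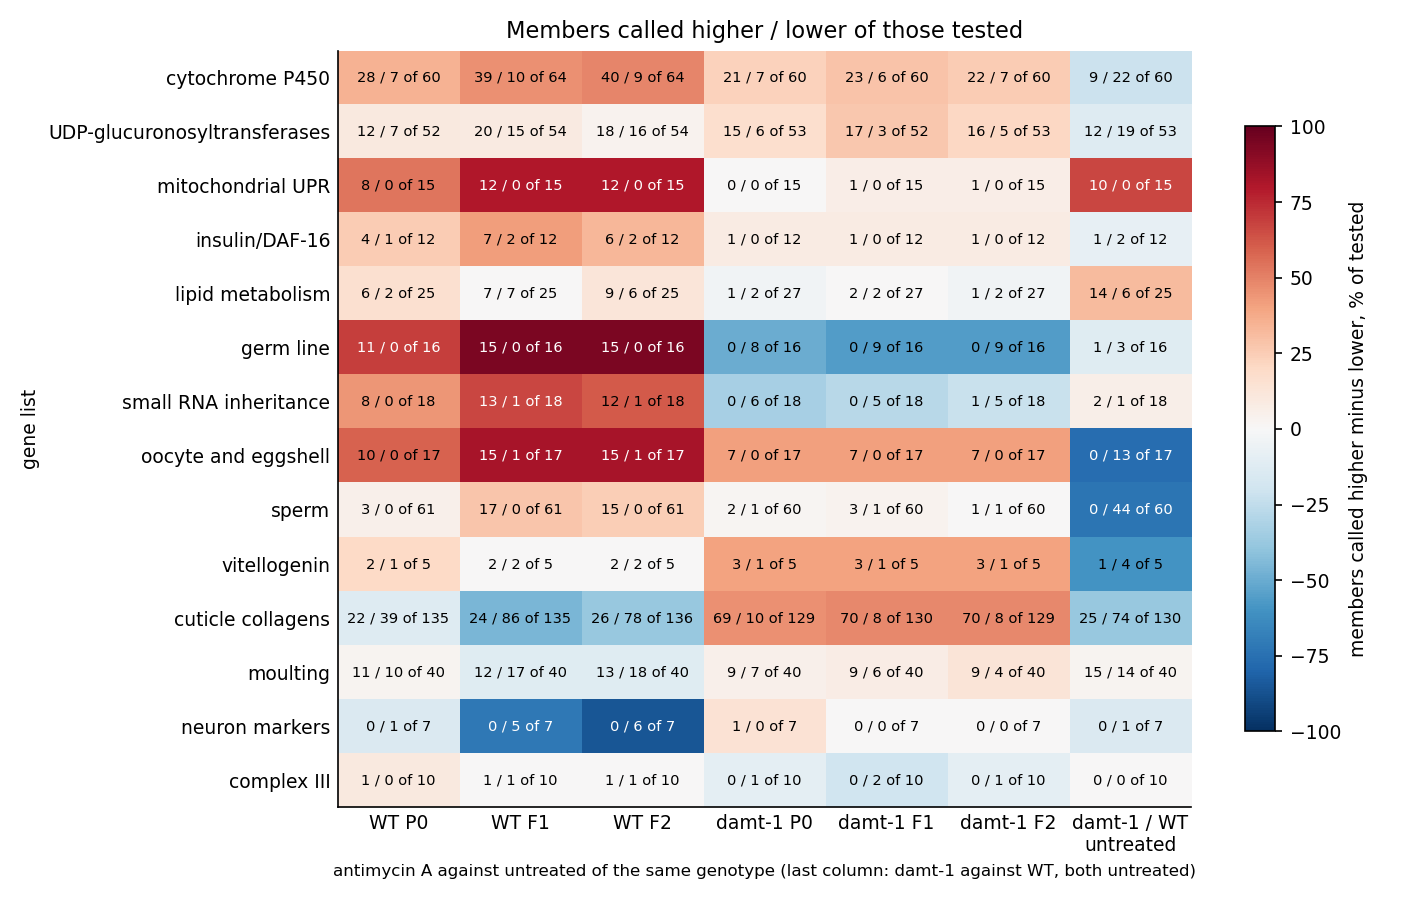
Members called higher and lower of those tested for 14 gene lists (vertical axis) in 7 comparisons (horizontal axis), coloured by the share higher minus the share lower. Germ line genes show 15 higher of 16 in wild type F1 and 9 lower of 16 in damt-1 F1, and sperm genes 44 lower of 60 in untreated damt-1 worms. With the low-density TMM factors the medians of the UDP-glucuronosyltransferase and lipid metabolism lists flipped sign in wild type F1 or F2, as all transcripts moved.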

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

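The results below were picked out because a response differed between genotypes or treated generations differed from each other. The tests of explanations in this part were all chosen after the result was seen.

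The adult cuticle transcripts col-19, col-62 and col-7 were close to 0 in the damt-1 untreated libraries. A scaling difference between libraries was argued against for these 3 transcripts. It would move all transcripts of a library alike. In damt-1 P0 against untreated worms col-19 was at 7.87, with a median of -0.005 over all transcripts. The scalings tried add little to this, since they shift all transcripts by far less than these changes. Over them and the 3 generations, the median of the adult cuticle list in treated against untreated damt-1 worms was at least 3.2 as fitted. With a member at 0 set to its bound it was 3.03, 2.77 and 2.77 under the main scaling. This median lies between the 3 members that rose and the others, the lowest of which was at -0.16 in P0. Less hypodermis in these worms was not excluded. Under every scaling tried at least 24 collagens were called higher in damt-1 untreated than in wild type untreated worms. A difference in stage could raise some collagens whatever the amount of hypodermis, so this count cannot decide. An earlier point of the last larval stage cannot be told apart from other causes: furrow collagens, made early in each larval cuticle cycle, had a median of 2.18 in the same comparison, but in treated against untreated damt-1 worms their medians were only -0.22, -0.16 and -0.17, and bli-1 and bli-2 of the adult list were higher in damt-1 untreated worms too. Other lists that could differ with stage were lower in damt-1 untreated worms. They were sperm genes (44 lower, 0 higher of 60), oocyte and eggshell genes (13 and 0 of 17) and vitellogenins (4 and 1 of 5). In treated against untreated damt-1 P0 worms, 2 sperm genes were higher and 1 lower of 60. Of 17 oocyte and eggshell genes 7 were higher and 0 lower there. An effect of the genotype on cuticle genes stays open and untested.

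Counts per nucleotide stopped near a common ceiling in all groups, which was picked out from the counts. A narrow range of true levels with every read counted was argued against, because the chi-square per degree of freedom between replicates of dense transcripts fell to 0.27, under what counting alone allows. Removal of reads that start at a position already used is consistent with its highest value over the groups, 0.43. If so, log2 changes of dense transcripts such as hsp-6 may be compressed. No biological explanation was tested.

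Wild type F1 and F2 were alike and apart from P0. An earlier point of the last larval stage in F1, for soma and germ line together, was argued against by oocyte and eggshell genes, higher in F1 than in P0 by a median of 0.49, although furrow collagens (median 0.75) and col-19 went the way this explanation needs, and the oocyte test was picked over the furrow one with both values seen. Other lists past camera with both correlations were sperm genes (13 higher, 0 lower of 61), germ line genes (8 and 0 of 16) and pharyngeal markers (4 and 1 of 9). Adult cuticle genes passed too, with 0 higher and 3 lower of 6, the way col-19 went. Whether F1 and F2 libraries came from 1 pool of worms or RNA cannot be told apart from separate worms: the mean chi-square per degree of freedom across F1 and F2 pairs was 1.24, inside the 1.18 to 1.33 of replicates within groups. An effect of the parents' treatment stays open and untested, as does a shift in timing of soma and germ line apart.

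The other results are given as values. The interaction of genotype and antimycin A was called in 2720 transcripts in P0, 5005 in F1 and 4968 in F2. In P0 its largest positive values were col-137 (11.89), abu-7 (11.21), abu-1 (11.07), abu-15 (10.81), col-62 (9.71) and idpc-2 (9.16), and its largest negative values mtl-1 (-5.65), hrg-2 (-5.2), acs-2 (-5.19), clec-17 (-5.06), drd-50 (-5.02) and cyp-13A5 (-4.58). In F1 they were col-137 (13.16), abu-1 (11.2), abu-7 (11.11), col-62 (10.96), abu-15 (10.58) and col-7 (9.69), and F07C4.6 (-7.99), F47H4.2 (-7.25), hrg-2 (-6.85), drd-50 (-6.83), D1086.1 (-6.43) and gpx-3 (-6.29). In F2 they were col-137 (13.14), col-62 (12.69), abu-15 (11.18), abu-1 (11.01), abu-7 (10.68) and idpc-2 (9.67), and ttr-21 (-8.25), gpx-3 (-6.58), ugt-40 (-6.27), hsd-3 (-6.19), D1086.1 (-6.05) and hrg-2 (-6.04). The fitted values of genes with a group at 0 depend on the prior count.

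Among the marker genes, the interactions in P0, F1 and F2 were 8.4, 9.21 and 9.28 for col-19, 0.24, 0.42 and 0.43 for hsp-4, -0.45, -0.49 and -0.51 for gst-4, and -1.91, -2.95 and -3.46 for sod-3. The interaction of damt-1 was -0.74 in F1 and that of hsp-60 was -0.26 in F2. List medians of the interaction were -0.79, -1.18 and -1.23 for germ line genes and 2.59, 4.71 and 4.55 for adult cuticle genes (2.59, 3.79 and 4.55 with members at 0 set to their bound).

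Between wild type F1 and P0 2798 transcripts were called and between F2 and P0 2809. Against P0, F1 had F08D12.3 at 3.57, M163.8 at 3.49, W01C9.2 at 3.41, C15C8.5 at -1.91, dct-5 at -1.7, nlp-25 at -1.61, col-19 at -0.75, hsp-4 at -0.14 and sod-3 at 1.2. F2 had M163.8 at 3.46, W01C9.2 at 3.45, F08D12.3 at 3.41, F31B12.3 at -1.55, C01G12.7 at -1.55, F09E5.12 at -1.51, col-19 at -0.85, hsp-4 at -0.15 and sod-3 at 1.24.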

How the results depend on the processing

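The density offset, the low-density TMM factors, F2 against F1, the analysis without cuticle, moulting and vitellogenin lists and the comparison with wild type untreated worms were chosen after the data were seen. Of 1209 pairs of a named gene and a comparison, 1174 were past the threshold, and 950 kept direction and side in every alternative run for single genes, which the replicate block and the log2 limit were not. Of the rest, 243 were weaker in some alternative, 7 that had not been called were called, and 11 reversed in sign, vha-6 and asb-1 being counted as weaker and as reversed.

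Called genes that reversed were vha-6 (-0.01) and asb-1 (-0.02) in wild type F1 with the low-density TMM factors. Uncalled ones that reversed with a library left out were damt-1 in damt-1 P0 (-0.34 to 0.02), F1 (-0.28 to 0.12) and untreated (-0.22 to 0.14, and 0.07 with the density offset and 0.06 with low-density TMM), sod-3 in damt-1 P0 (-0.31 to 0.31, 0.11 with another left out), F1 (-0.15 to 0.47, -0.01 with another left out) and F2 (-0.61 to 0.01), hsp-60 in damt-1 F2 (-0.02, also by library size only), and gst-4 between untreated genotypes (-0.1 to 0.01, and 0.05 with low-density TMM). The hsp-60 interaction in F1 was 0.01 with low-density TMM. The cause was not tested.

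DESeq2 called 1489 transcripts in wild type P0, 1034, 1043 and 1020 in damt-1 P0, F1 and F2, 1737 for the P0 interaction, and 1361 and 1432 for wild type F1 and F2 against P0. Against wild type untreated worms, damt-1 P0, F1 and F2 gave 4504, 4631 and 4646 calls, which by construction include the genotype. The cause of the DESeq2 shifts was not tested. A log2 limit of 1 left 474, 1563 and 1636 calls in wild type P0, F1 and F2, 501, 468 and 494 in damt-1, 1683, 1533, 2204 and 2141 between genotypes untreated and in P0, F1 and F2, 1017, 2161 and 2161 for the interactions, and 364 and 371 for F1 and F2 against P0, since it drops smaller changes. Calls shared at this limit, higher and lower, were 363 and 51 (wild type P0 and F1), 369 and 64 (P0 and F2), 918 and 344 (F1 and F2), and 336 and 34, 338 and 34, and 333 and 28 for the same pairs in damt-1.

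With a library left out, calls ran from 1793 to 2004 in wild type P0, 4743 to 5177 in F1, 4810 to 4961 in F2, 1205 to 1341, 1171 to 1223 and 1198 to 1389 in damt-1, and 3803 to 4037 between untreated genotypes. Between wild type F1 and P0 they ran from 1633 without F1 replicate 2 to 2196 without F1 replicate 1, and between F2 and P0 from 1801 without F2 replicate 2 to 1952 without P0 replicate 2. Fewer libraries test less. Correlations between generations ran from 0.84 to 0.86 for wild type P0 with F1 and with F2, were 0.95 for F1 with F2, and ran from 0.9 to 0.91 for the damt-1 pairs. With a mean of at least 10 CPM they were 0.9, 0.9 and 0.98 in wild type and 0.96 in each damt-1 pair. Lists called with an estimated correlation and with fry were 4 and 21, 3 and 26, and 3 and 26 in wild type P0, F1 and F2, 5 and 17, 5 and 17, and 5 and 16 in damt-1, 1 and 26 between untreated genotypes, and 2 and 15, 2 and 26, and 2 and 23 for the interactions. The replicate block moved no count by more than 1.5 times. At these totals the smallest simulated changes were recovered in 30% of transcripts, so smaller changes may be missed. Without wild type P0 replicate 2, 1793 calls were left in wild type P0.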

Other observations

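The test of a hypothesis in this part was chosen after its result was seen. Genes of the response to intracellular pathogens were not among the lists called, yet single members rose in wild type. The pals genes belong to a family induced by viruses and microsporidia. In wild type worms pals-6 rose from 0.865 ± 0.11 CPM to 24.6 ± 0.086, 57.5 ± 3.9 and 54.5 ± 1.3 CPM in P0, F1 and F2 (log2 4.77 ± 0.35, 6 ± 0.3 and 5.92 ± 0.3), and pals-34 by 2.24 ± 0.33, 2.97 ± 0.3 and 2.88 ± 0.31. In damt-1 worms pals-6 stood at 2.33 ± 0.46, 3.09 ± 0.67 and 1.3 ± 1 CPM, and its interaction was -3.96 ± 0.8, -4.78 ± 0.81 and -5.88 ± 0.87. Of 19 members 5 rose and 0 fell in wild type P0 (the same adjusted over the list alone, camera adjusted p = 0.18).

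Single chromatin genes linked to inheritance differed in their response between the genotypes, though the list was not called. The histone methyltransferase gene mes-4, which keeps germ line genes marked, rose in wild type from 61.3 ± 2.7 CPM to 94.7 ± 4.8, 110 ± 0.97 and 111 ± 0.84 CPM in P0, F1 and F2 and fell in damt-1 from 108 ± 8.7 CPM to 87 ± 0.28, 79 ± 1.4 and 83.3 ± 2.6 CPM. Its mean in damt-1 was thus above that of wild type when untreated and below it in each treated group. The H3K9 methyltransferase gene met-2 rose by 0.6 ± 0.06, 0.82 ± 0.06 and 0.82 ± 0.06 in wild type, and its interactions were -0.62 ± 0.09, -0.93 ± 0.09 and -0.83 ± 0.09. Of 14 members, 4 rose and 0 fell in wild type P0 and 0 rose and 3 fell in damt-1 P0 (the same adjusted over the list alone, camera adjusted p = 0.23 and 0.29). The interaction was higher in 0 and lower in 5, 6 and 5 (the same adjusted over the list alone, camera adjusted p = 0.13, 0.15 and 0.25). Germ line genes went the same way, with interaction medians of -0.79, -1.18 and -1.23 and 13, 14 and 16 of 16 lower. In whole worms the values of mes-4 and met-2 are thus not parted from that shift.

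A hypothesis was that the wild type step from P0 to F1 moves transcripts the way the damt-1 untreated libraries already differ from wild type. These comparisons share no library. Across 12417 transcripts they correlated at r = 0.32 (0.29 to 0.34 over 1000 bootstrap draws of transcripts, which are not independent), with 1423 transcripts called in both the same way and 381 the opposite way. The step from P0 to F2 gave 0.34. Against the damt-1 response to treatment in P0 the wild type step gave r = -0.21. That response takes the same damt-1 untreated libraries with the opposite sign, so this r is no separate result. The r of 0.32 would go with a part of the change being held in common. In the wild type step and in untreated damt-1 worms alike, furrow collagens were higher in 6 of 6 (medians 0.75 and 2.18). Collagens were lower in 68 and higher in 12 of 135 in the step, and lower in 74 and higher in 25 of 130 in untreated damt-1 worms. A difference in stage is thus not excluded, and the cause was not tested. The change in common did not take in oocyte and eggshell genes, of which 15 were higher and 0 lower of 17 in the wild type step (15 and 1 adjusted over the list alone) and 0 higher and 13 lower in untreated damt-1 worms (the same adjusted over the list alone), nor sperm genes, 13 higher and 0 lower of 61 (15 and 0) against 0 higher and 44 lower of 60 (0 and 48).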
